A study of Mus musculus with 7 samples.

How the data were processed

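RNA was measured by sequencing in microglia, the resident macrophages of the brain, sorted from the cortex of mice at postnatal day 30. The 4 cKO libraries came from mice that carried 2 floxed alleles of Srgap2 and the Tmem119-CreERT2 driver, a tamoxifen-inducible recombinase expressed in microglia. The 3 WT libraries came from floxed littermates without the recombinase. Per the labels' protocols, mice of both groups received tamoxifen by gavage in 2 doses of 75 ug per g at postnatal days 8 and 10, cells were gated as CD11b-positive, CD45-low and CX3CR1-positive, and libraries were made from poly(A)-selected RNA. Each library is from a separate numbered mouse per the labels, so the p-values measure the spread between mice. The recombinase was present only in the cKO group, so effects of the recombinase and of the Srgap2 deletion are not separated by the design. Sex, litter, and sort and sequencing batches are not given in the labels.

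The authors deposited one table of whole-number counts per gene, which were not normalized. Per the submitters' processing notes, DRAGEN and the GRCm39 build were used; the gene annotation, the counting rule and the strand setting are not given in the sources used here. Counts were taken per gene symbol as deposited. The table held 23420 genes, of which 7033 had no count in any library and 0 were mitochondrially encoded, so a mitochondrial share was not computed. Gene symbols were compared with a reference gene table of another assembly (GRCm38.p6): 21571 were its current symbols, 1712 were synonyms only and 137 were in neither column. That table was used only for names and for which genes neighbour each other, and the transcripts of GENCODE M21 only for GC content and transcript length. Without a stated counting rule, reads of genes with near-identical copies, such as ribosomal protein genes, Tmsb4x, Tmsb10, Cfl1, Ptma, Eef1a1 and Gapdh with their processed pseudogenes, have an uncertain assignment, and the same holds for overlapping and antisense genes.

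Total counts ranged from 27016173 to 35707304 per library. Pairs of libraries within a group differed by far more than sampling noise (chi-square per degree of freedom from 18.0 to 93.1), so none was treated as a repeat of another. Genes were kept with filterByExpr of edgeR (version 4.0.16, with limma 3.58.1, in R 4.3.3; least count 10, least total count 15), which left 11991 genes. Library sizes were scaled with TMM factors, and cKO was compared with WT by the quasi-likelihood F test of edgeR with the robust option and no covariate. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Levels are TMM-scaled CPM, the count of a gene relative to the scaled library size, given as mean ± SD, and log2 CPM used a prior count of 2. For Srgap2, Tmem119 and Esr1 a two-sided exact permutation test of the difference in mean log2 CPM was made over the 35 ways of dividing 7 libraries into 4 and 3.

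Before the data were examined, 33 gene lists, the groups, the tests and the rule for naming genes were fixed. Of 1101 symbols in the lists, 1069 were matched, 19 of them by a synonym. Lists with at least 5 members tested were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 30 lists tested. The Erythroid cells list (2 members tested), the mitochondrially encoded list (0) and the sex-linked list were not tested. Each list was also tested with an estimated correlation and with fry, which asks whether the members move on balance one way and makes no comparison with other genes. The genes named are Srgap2, Srgap1, Srgap3, Tmem119, P2ry12, Cx3cr1, Xist and Ddx3y; up to 12 rising and 12 falling genes with the largest changes among those past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups, with predicted genes only counted; and up to 4 members of each list described, those past the threshold first and otherwise those with the smallest p. Other genes are named only where the text says that they were chosen after their values were seen. Some genes and a list that these rules take are not reported here, though they remain in the counts.

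The alternatives fixed beforehand were RLE and upper-quartile factors, DESeq2 (version 1.42.0), limma-voom without and with sample quality weights, edgeR without the robust option, no filter, a filter of 1 CPM in at least 3 libraries, leaving out each library, the replicate number as a block, the run of mouse numbers as a block, log2 CPM of Xist as a covariate, a test against a fold change of 1.2, and lists without the members of the ex vivo activation list. Offsets per library for GC content and transcript length (loess, span 0.3; values for 99.3% of the genes tested), the same offsets with the Xist covariate, and the mouse-number block with the Xist covariate were added after seeing the data.

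The procedure was tested on simulated counts for 4 and 3 libraries and 11825 genes. It recovered 2% of the genes with the smallest simulated change, which was under 1.5-fold, 38% of those changed 1.5-fold, 78% of those changed 2-fold and 98% of those changed 3-fold, and 11 of its 119 calls were false. A list changed 1.3-fold was called, and 0 of 20 unchanged lists were. The simulated genes were independent of each other, so the list result does not cover members that vary together. Figures were drawn with matplotlib 3.10.9.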

Results

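The expression of 11991 genes was compared between cortical microglia of mice in which Srgap2 had been deleted in microglia from postnatal day 8 (cKO, n = 4) and those of floxed littermates without the recombinase (WT, n = 3), at postnatal day 30. The series asks how microglia without Srgap2, which encodes a protein with an F-BAR domain that acts on membranes and the actin cytoskeleton, differ from control microglia in the undisturbed juvenile brain. Total counts were 27025270, 30388655, 27388879 and 35213711 in cKO replicates 1 to 4, and 27016173, 30983968 and 35707304 in WT replicates 1 to 3.

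Srgap2 was lower in every cKO library than in every WT library. Its level was 344, 257, 275 and 212 CPM in cKO replicates 1 to 4, against 979, 691 and 693 CPM in WT replicates 1 to 3. The mean was 272 ± 55.0 CPM (SD, n = 4) in cKO and 788 ± 165 CPM (SD, n = 3) in WT, which left 34.5% of the WT level. The log2 fold change was −1.53 (SE 0.17, adjusted p = 0.0053), and the two-sided exact permutation p was 0.029, the smallest that 35 splits can give. The counts cover the whole gene, so reads outside the deleted part are included. Per-gene counts also do not show in what share of the cells the deletion took place. The paralogs were scarce in these cells. Srgap3 was at 3.90 ± 0.71 CPM in cKO and 5.89 ± 0.47 CPM in WT, a difference that did not pass (log2 fold change −0.60, SE 0.19, adjusted p = 0.16), and Srgap1 had from 0 to 3 counts per library and was not tested.

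The genes that passed the threshold were mostly higher in cKO: 38 rose and 5 fell, Srgap2 included, 43 in all, and 1981 genes had an unadjusted value under 0.05. Lsp1, a leukocyte protein that binds F-actin, rose from 64.8 ± 13.6 to 240 ± 33.0 CPM (3.71-fold; log2 fold change 1.89, SE 0.16, adjusted p = 0.00073). Cnn2, the actin-binding protein calponin 2, rose from 21.9 ± 8.89 to 85.5 ± 24.9 CPM (log2 fold change 1.97, SE 0.29, adjusted p = 0.025). Further cytoskeletal genes among the largest rises were Tpm4, a tropomyosin (0.93, SE 0.11, adjusted p = 0.0068), Stmn1, which destabilises microtubules (1.16, SE 0.17), Tmsb10, which sequesters actin monomers (1.10, SE 0.18), Cfl1, which severs actin filaments (0.89, SE 0.13), and Mtpn, which binds actin capping protein (0.73, SE 0.11). Other large rises were those of Ptgr1 (0.82, SE 0.15), the glycolipid transfer protein gene Gltp (0.76, SE 0.11) and the integrin-associated Rsu1 (0.75, SE 0.11). Abcg1, a cholesterol exporter, fell from 277 ± 11.5 to 144 ± 7.47 CPM (−0.94, SE 0.10, adjusted p = 0.0026), and Gpr157 fell from 109 ± 16.7 to 63.3 ± 4.56 CPM (−0.78, SE 0.12, adjusted p = 0.028). The number of genes depended on single libraries, and leaving one out also lowers the power of the test. It was 142 without cKO replicate 1, 6 without cKO replicate 2, 6 without cKO replicate 3 and 44 without cKO replicate 4, of which 35 were among the 43. It was 10 without WT replicate 1, 4 without WT replicate 2 and 6 without WT replicate 3. Of the 35 ways of dividing the libraries into 4 and 3, 3 gave at least 43 genes, the real one included. All 43 genes kept their direction when any one library was left out, and Srgap2, Esr1, Lsp1 and Abcg1 also passed each time.

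**Figure D1:**
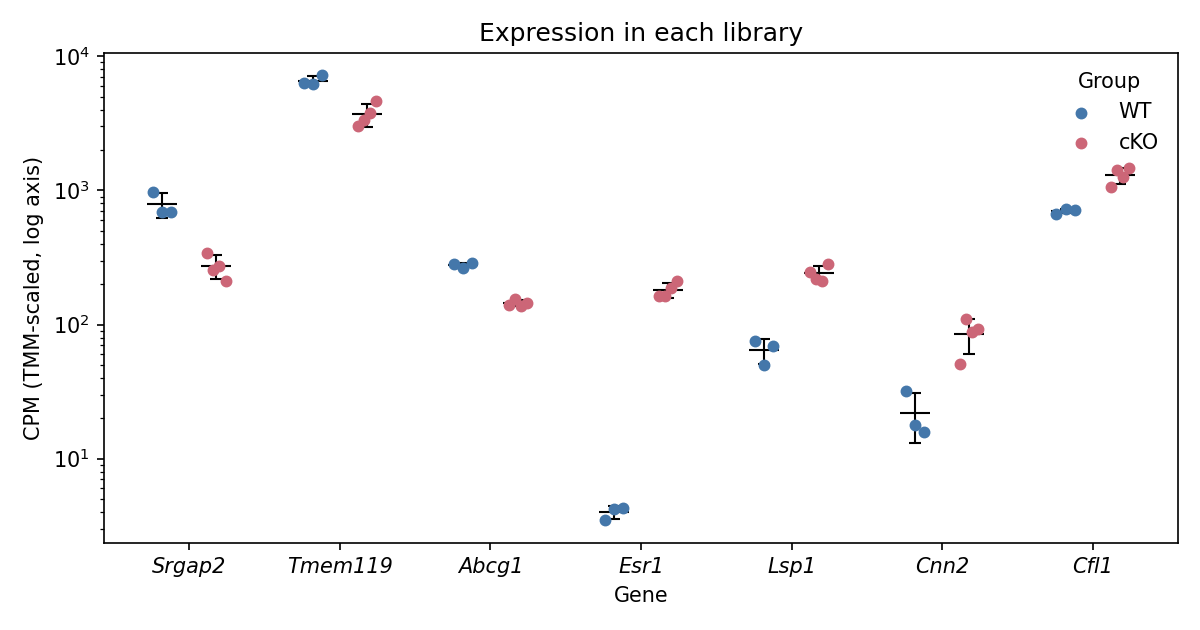
CPM on a log axis for 7 genes in each library, with WT in blue (n = 3) and cKO in red (n = 4); bars are the mean and SD. For each of the 7 genes, every cKO library lies on one side of every WT library. The rule for naming genes with the largest changes required this, while Srgap2 and Tmem119 were to be named in any case. Srgap2 is at 34.5% of the WT level and Esr1 is 45.2-fold higher in cKO.

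Esr1, the estrogen receptor alpha gene, showed the largest rise of the genes named by the rule, and Tmem119, a marker of mature microglia, fell. Esr1 was at 181 ± 23.7 CPM in cKO and 3.99 ± 0.45 CPM in WT (45.2-fold; log2 fold change 5.50, SE 0.16, adjusted p = 1.1e-08). Tmem119 was at 3707 ± 716 CPM in cKO and 6558 ± 571 CPM in WT (log2 fold change −0.82, SE 0.15, adjusted p = 0.046). The two-sided exact permutation p was 0.029 for each. The CreERT2 recombinase carries a modified ligand-binding domain of this receptor and is expressed from the Tmem119 locus, and only cKO mice have it. The Tmem119 call was lost without cKO replicate 2, cKO replicate 3 or any one WT library, with log2 fold changes from −0.75 to −0.88. Other microglial genes did not pass: P2ry12 was at 2910 ± 466 CPM in cKO and 2738 ± 556 CPM in WT (adjusted p = 0.84), and Cx3cr1, a gene of the sort, at 6521 ± 326 and 7603 ± 547 CPM (adjusted p = 0.33).

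The actin cytoskeleton and motility list had a median log2 fold change of 0.25. It passed camera with the preset correlation (adjusted p = 2.6e-12) and fry (adjusted p = 0.046), but not camera with an estimated correlation (adjusted p = 0.28). Of 49 members tested, 4 rose, 0 fell and 45 did not pass; 17 rose when adjusted over the list alone, and 41 had a fold change above 0. Besides Cfl1, the members that rose were Tmsb4x (0.67, SE 0.11, adjusted p = 0.030), which binds actin monomers, and Arpc2 (0.63, SE 0.10, adjusted p = 0.032) and Arpc5 (0.54, SE 0.10, adjusted p = 0.048), subunits of the Arp2/3 complex that nucleates branched actin. The mean log2 CPM of the list was 7.81, 7.96, 7.91 and 7.99 in cKO replicates 1 to 4, and 7.68, 7.64 and 7.63 in WT replicates 1 to 3. Among the 35 splits of the libraries, 2 gave a camera p for this list as small as the real one, the real one included. The other was the real division with only cKO replicate 1 moved to the WT side.

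**Figure D2:**
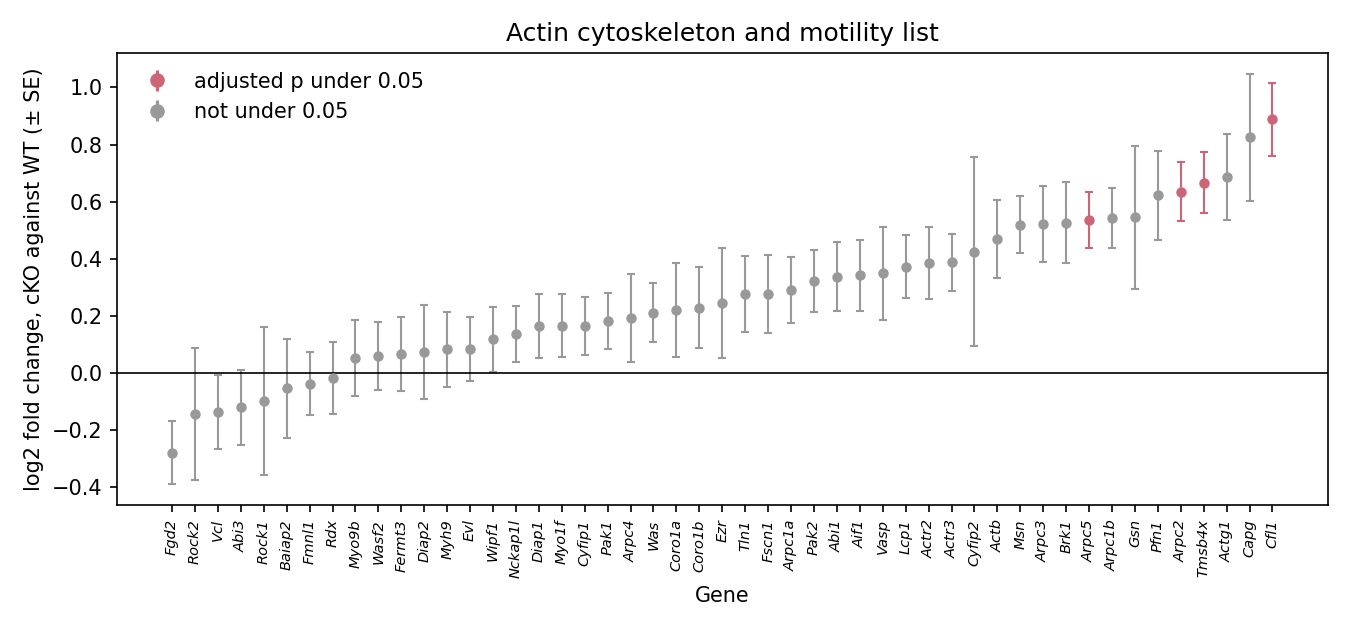
Log2 fold change of cKO against WT, with its standard error, for the 49 members tested of the actin cytoskeleton and motility list, ordered by size. Red points are the 4 members with an adjusted p under 0.05 over all genes tested, and 41 of the 49 points lie above 0.

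Of the 30 lists tested, 10 passed camera with the preset correlation, 0 passed with an estimated correlation, and 3 passed fry: the actin list, the cell cycle list and the purinergic list. Of the 35 ways of dividing the libraries into 4 and 3, 16 gave at least 10 lists, the real one included, so a list that passed with the preset correlation alone is given here with its values and not as a group that changed. In the cell cycle and proliferation list, 2 of 35 members rose, Stmn1 and Rrm2, a subunit of ribonucleotide reductase (2.77, SE 0.49, adjusted p = 0.045), and 10 rose when adjusted over the list alone. Its median was 0.40 (adjusted p = 2.6e-08, and adjusted p = 0.28 with an estimated correlation). Some members were near the floor: Rrm2 was at 0.74 ± 0.22 CPM in cKO and 0.11 ± 0.03 CPM in WT, and Top2a and Mki67, which did not pass, were at 1.56 ± 0.58 and 1.01 ± 0.24 CPM in cKO. With the filter of 1 CPM in at least 3 libraries, 25 members were tested and the median was 0.36. The cytosolic ribosomal protein list had 0 of 78 members past the threshold and 66 when adjusted over the list alone, with a median of 0.43 (adjusted p = 4.9e-31, and adjusted p = 0.54 with an estimated correlation). The oxidative phosphorylation list had 0 of 73 members past the threshold and 16 when adjusted over the list alone, with a median of 0.39 (adjusted p = 7.1e-21, and adjusted p = 0.54 with an estimated correlation). With offsets for GC content and transcript length, an alternative chosen after seeing the data, the medians were 0.27 and 0.22. Glycolysis and hypoxia genes had a median of 0.24 with 0 of 28 past the threshold, and 9 rose and 1 fell when adjusted over the list alone (adjusted p = 0.0037, and adjusted p = 0.60 with an estimated correlation). The mean log2 CPM of these genes was 5.85 in cKO replicate 4, from 5.37 to 5.59 in the other cKO libraries and from 5.31 to 5.42 in WT, and without cKO replicate 4 the median was 0.11.

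**Figure D3:**
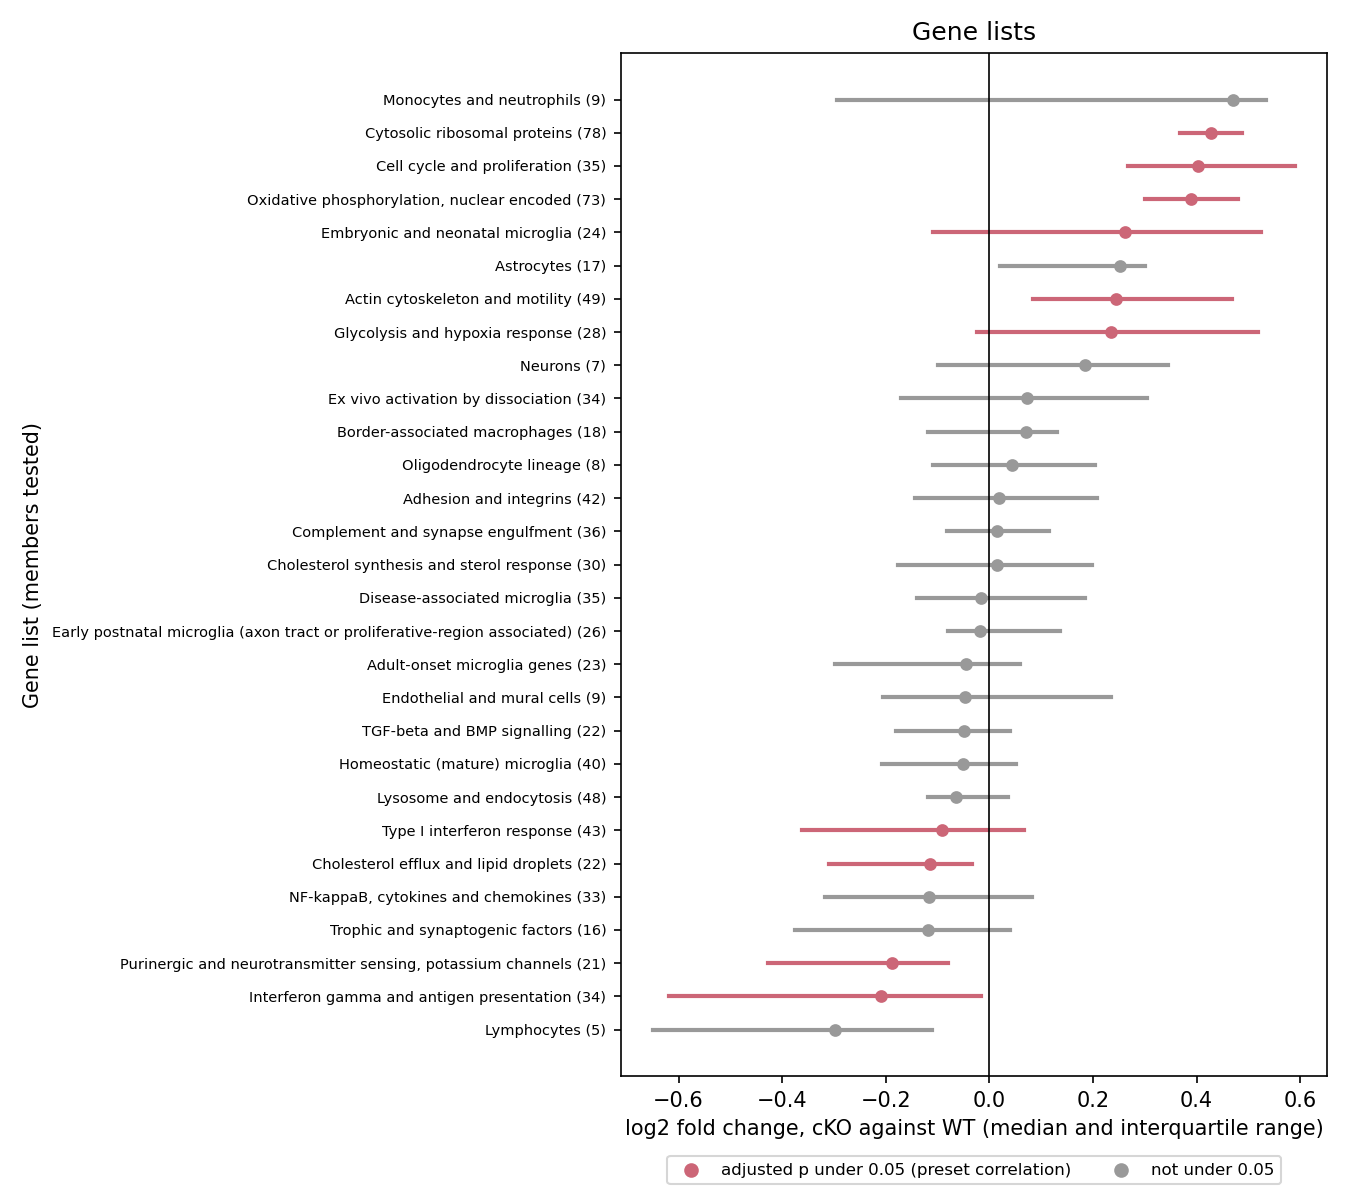
Median log2 fold change of cKO against WT (points) and interquartile range (lines) of the members of the gene lists described, with the number of members in parentheses. The 10 lists in red had an adjusted p under 0.05 by camera with the preset correlation, of which 0 passed with an estimated correlation.

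Lists of microglial maturation showed few single-gene changes. In the embryonic and neonatal microglia list, 1 of 24 members rose, Tmsb10, and the median was 0.26 (adjusted p = 0.010, and adjusted p = 0.60 with an estimated correlation). The mean log2 CPM of the list was 3.70 in WT replicate 1, against 4.34 and 4.28 in the other WT libraries and from 4.16 to 4.45 in cKO. Without WT replicate 1 the median was 0.08 and the list did not pass, while it was 0.41 without WT replicate 2 and 0.40 without WT replicate 3; the list also did not pass with sample quality weights (median 0.14) or with GC content and length offsets (0.11). In the homeostatic list, 1 of 40 members fell, Tmem119, and the median was −0.05 (adjusted p = 0.20). It was −0.08 without cKO replicate 2, −0.08 without cKO replicate 4, −0.09 without WT replicate 1 and −0.14 with GC content and length offsets. In the adult-onset list the 1 of 23 members that fell was again Tmem119 (median −0.05, adjusted p = 0.081). The adult-onset list did pass without cKO replicate 4 (median −0.11, adjusted p = 0.037), WT replicate 1 (−0.08, adjusted p = 0.020) or WT replicate 2 (−0.08, adjusted p = 0.040) and with GC content and length offsets (−0.19, adjusted p = 0.0051). The early postnatal list had 0 of 26 members past the threshold (adjusted p = 0.53) and the disease-associated list 0 of 35 (adjusted p = 0.33). In these last lists the median, −0.02 in both, was below 0 while the mean, 0.06 in both, and the direction of the test were above 0. The disease-associated list passed on the higher side without cKO replicate 1 (median 0.03, adjusted p = 0.041) or WT replicate 2 (0.12, adjusted p = 0.0089) and with the Xist covariate (0.14, adjusted p = 0.035), while its median was −0.12 without WT replicate 1. The early postnatal median was −0.08 without WT replicate 1 and 0.08 without WT replicate 2. In the adhesion and integrin list (0 of 42, adjusted p = 0.68) the median was 0.02 and the mean −0.02, and the median was −0.07 without cKO replicate 4.

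The lists on the lower side held few genes past the threshold. In the cholesterol efflux list, Abcg1 was the 1 of 22 members that fell; the median was −0.11 (adjusted p = 0.010, and adjusted p = 0.54 with an estimated correlation). The list did not pass without WT replicate 3 (median −0.08) or with the Xist covariate (−0.08), and the median was −0.22 without WT replicate 1 and −0.17 without cKO replicate 4. The cholesterol synthesis list, with 30 members tested, did not pass (median 0.02, adjusted p = 0.39). Its median was 0.08 without WT replicate 3 and −0.06 without WT replicate 1. The interferon gamma and antigen presentation list had 0 of 34 members past the threshold and 4 lower when adjusted over the list alone, with a median of −0.21 (adjusted p = 0.00019, and adjusted p = 0.54 with an estimated correlation). The WT libraries were apart from each other: the mean log2 CPM of the list was 4.46 in WT replicate 1, no higher than in any cKO library (4.46 to 4.55), and 5.06 and 4.99 in WT replicates 2 and 3. Its members with the smallest p were H2-Q4 (−0.71, SE 0.14, adjusted p = 0.060) and Tap1 (−0.54, SE 0.12, adjusted p = 0.096). The type I interferon list had a median of −0.09 with 0 of 43 past the threshold (adjusted p = 0.017, and adjusted p = 0.72 with an estimated correlation); it did not pass without cKO replicate 2 (median −0.01), cKO replicate 4 (−0.04) or WT replicate 2 (−0.07), and the median was −0.30 without cKO replicate 1, −0.16 without WT replicate 1 and −0.22 with the Xist covariate. The purinergic, neurotransmitter and potassium channel list had 0 of 21 members past the threshold, with a median of −0.19 (adjusted p = 0.0049, and adjusted p = 0.34 with an estimated correlation), which was −0.12 without WT replicate 1.

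The remaining biology lists did not pass in the main fit and held 0 genes past the threshold. These were the lists of complement and synapse engulfment (36 members, median 0.02, adjusted p = 0.68), lysosome and endocytosis (48, −0.07, adjusted p = 0.45), NF-kappaB, cytokines and chemokines (33, −0.12, adjusted p = 0.11), TGF-beta and BMP signalling (22, −0.05, adjusted p = 0.33) and trophic and synaptogenic factors (16, −0.12, adjusted p = 0.33). The NF-kappaB list did pass without cKO replicate 4 (median −0.14, adjusted p = 0.043) or WT replicate 1 (−0.18, adjusted p = 0.0072), with sample quality weights (−0.11, adjusted p = 0.024) and with GC content and length offsets (−0.16, adjusted p = 0.012), and its median was −0.06 without WT replicate 2. The lysosome list passed with sample quality weights (median −0.09, adjusted p = 0.044) and, at the limit, without WT replicate 1 (−0.09). Its median was −0.0029 without cKO replicate 1, −0.015 without WT replicate 2, −0.0022 without WT replicate 3 and 0.013 with the Xist covariate. The TGF-beta median was 0.04 without WT replicate 1, −0.09 without cKO replicate 3 and −0.09 without WT replicate 3. The trophic median was −0.05 without WT replicate 2 and −0.06 with GC content and length offsets. The complement median was 0.04 without WT replicate 2 and 0.0068 without cKO replicate 2. Genes induced by dissociation did not pass as a list (34, 0.07, adjusted p = 0.68). The median was −0.03 without cKO replicate 3 and 0.15 without WT replicate 3.

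Markers of other cell types did not pass as lists. The adjusted p was 0.68 for border-associated macrophages (median 0.07), 0.44 for monocytes and neutrophils (0.47, 9 members), 0.21 for lymphocytes (−0.30, 5 members), 0.32 for astrocytes (0.25), 0.68 for the oligodendrocyte lineage (0.04), 0.68 for neurons (0.19) and 0.68 for endothelial and mural cells (−0.05). None passed when any one library was left out, but several medians rested on single libraries. That of monocytes and neutrophils was −0.0015 without WT replicate 1 and 0.12 without cKO replicate 4. That of astrocytes was −0.0068 without cKO replicate 2 and 0.03 without WT replicate 2. That of neurons was −0.02 without WT replicate 1 and 0.39 without WT replicate 3. That of lymphocytes was −0.21 without WT replicate 1 and −0.54 without WT replicate 3. That of border-associated macrophages was −0.07 without cKO replicate 1. That of the oligodendrocyte lineage was 0.32 without WT replicate 1 and −0.16 without cKO replicate 2. That of endothelial and mural cells was −0.13 without cKO replicate 1 and −0.00094 without WT replicate 3. The 2 erythroid genes tested had a median of 1.04 and did not pass. The libraries also differed in ways that the genotype did not explain. The first principal component held 32.3% of the variance and the second, which separated the groups, 24.8%. Xist, transcribed from the inactive X chromosome, was at 69.4 and 144 CPM in cKO replicates 2 and 4 and at 243 and 127 CPM in WT replicates 2 and 3, and at most 0.66 CPM in the other libraries. The Y-linked Ddx3y was at 27.9 and 27.2 CPM in cKO replicates 1 and 3 and 30.4 CPM in WT replicate 1. Across genes within one library, which are not independent replicates, the rank correlation of deviation from the mean level with GC content ranged from −0.50 in cKO replicate 1 to 0.42 in cKO replicate 4. This correlation and the first principal component were both above 0 in each library with Xist and below 0 in each of the others. With Xist as a covariate 1056 genes passed, 745 higher and 311 lower in cKO, among them 42 of the 43.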

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

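The tests in this part were chosen after the results were seen, with exceptions. The leukocyte, Esr1 and Tmem119 tests and the rule for reading the GC content results were also changed after a first run. The Xist covariate, the fits without a library and the estimated correlation were fixed before the data were examined, and the counts of splits for the actin list and for the lists were set before those counts were known.

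Among 126 genes, 31 lists and the total count, 158 values in all, 8 had one cKO library far from the other cKO libraries, where chance gives about 1 in 20, or 7.9. The gap to the nearest library on the log2 CPM scale, as a share of the range of the 4, was 0.839 for Btg2 (cKO replicate 3, 198 CPM, the others from 186 to 188), 0.869 for Mylip (replicate 4, 323 CPM, the others from 369 to 376) and 0.840 for Dgat1 (replicate 4, 32.4 CPM). It was 0.872 for Top2a (replicate 4, 2.42 CPM), 0.942 for Pmepa1 (replicate 4, 589 CPM, the others from 526 to 530) and 0.905 for Il7r (replicate 4, 22.7 CPM). For Adora3 it was 0.843 and for Kdr 0.864 (replicate 1, 141 and 3.71 CPM). The groups of 3 were not tested.

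The 43 genes past the threshold cannot be separated from a chance division of the libraries by their number alone. Of the 35 ways of dividing 7 libraries into 4 and 3, 3 gave at least 43 genes, the real one included, and the highest of the others gave 122. That split set cKO replicates 2 and 4 and WT replicates 2 and 3, the libraries with Xist, against the rest. This points to a structure of the samples that the groups do not follow. The rank correlation with GC content was from 0.07 to 0.42 in the libraries with Xist and from −0.50 to −0.0029 in the rest. Ddx3y was at most 0.18 CPM in the libraries with Xist and from 27.2 to 30.4 CPM in the rest. The split with 122 genes thus follows sex as read from Xist and Ddx3y, and is not an arbitrary one. Whether sex or GC content gave its genes is not told apart. The remaining split of the 3, with 58 genes, differed from that with 122 only in where WT replicate 2 stood. With the Xist covariate the groups gave 1056 genes, and the splits were not refitted with it. The lists fared worse: 16 of the 35 splits gave at least 10 lists, and the highest of the others gave 19. Srgap2, Esr1, Lsp1 and Abcg1 passed in each fit that left out a library. Those fits reuse the libraries that gave the calls, so they are not a separate test of chance. Of these genes only Srgap2 and Esr1 were compared over the 35 splits, with a two-sided exact permutation p of 0.029 for each.

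The first pattern is the higher level of the actin list, which did not pass with an estimated correlation (adjusted p = 0.28). Of the 35 splits, 2 gave a camera p as small, the real one included. The other, with a camera p of 1.0e-13, was the real division with only cKO replicate 1 moved to the WT side. It therefore shares most of the real contrast. Chance is not excluded here either, since the real division, with a camera p of 2.6e-13, did not give the smallest value of the 35 splits. GC content or transcript length as the whole cause is argued against by a median of 0.26 with offsets for both, against 0.25 without, and sex of the animals as the whole cause by 0.29 with the Xist covariate. With the offsets and the Xist covariate together the median was 0.24. With the offsets and an estimated correlation the list did not pass (adjusted p = 0.17). Whether blood leukocytes in the sort added to the rise is not settled by their markers. The summed CPM of 36 markers under 10 CPM in WT rose by 0.048% of the rise of the actin list. These markers summed to 17.89 CPM (SD 3.22) in WT, against 24155 CPM for the actin list. Even a large relative rise of the markers would thus give a small ratio. Their rise of 3.15 CPM was no larger than the WT SD. S100a4 was at 1.04 CPM, S100a6 at 0.50 CPM and Ccr2 at 2.49 CPM in cKO. Csf3r, left out of the sum with Il7r and Cd79b for its higher level in WT, was at 384 CPM in cKO and 483 CPM in WT. A response to loss of Srgap2 or to the recombinase stays open and untested. For the ribosomal protein and oxidative phosphorylation lists the offsets left medians of 0.27 and 0.22, from 0.43 and 0.39. With the offsets and an estimated correlation these lists did not pass (adjusted p = 0.27 and 0.34). GC content and length may thus account for a part, and whether they account for the whole is not settled.

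The second pattern is the rise of Esr1 with the fall of Tmem119. A fall of the whole homeostatic list by the size of the Tmem119 fall is argued against by the other 39 members, with a median of −0.048 (SD 0.20) and 0 at or below the Tmem119 value of −0.82. A smaller shared fall is not excluded by these values. Reads from the receptor domain of the recombinase may have been counted as Esr1: the lowest cKO library was 37.9 times the highest WT library, but expression of Esr1 itself cannot be told apart from this, because per-gene counts hold no position and only cKO mice carry the recombinase. Likewise the recombinase allele may lower Tmem119 itself: the highest cKO library was at 0.756 of the lowest WT library, and an effect of Srgap2 loss cannot be told apart from it in this design.

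The third pattern is Serinc3, chosen after its values were seen, which lay at 3 levels: 5100 CPM in WT replicate 1, from 2711 to 3059 CPM in the cKO libraries, and 831 and 825 CPM in WT replicates 2 and 3. GC content or length is argued against by a log2 gap of 2.61 between WT replicate 1 and the mean of the other WT libraries with the offsets. A haplotype that segregates among the mice may place neighbouring genes in the same order of libraries. Of the 20 nearest genes tested on the GRCm38.p6 order, 2 did (Pkig and Ttpal), as did 2.38% of all genes tested, and 8.50% of other windows held as many. By this count a haplotype cannot be told apart from chance with 7 libraries. The count takes the order of the libraries and not the size of the steps. Pkig was at 107 CPM in WT replicate 1, from 78.0 to 91.9 CPM in cKO, and at 35.3 and 34.9 CPM in WT replicates 2 and 3. No biological explanation was tested.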

How the results depend on the processing

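Srgap2 kept its direction and passed under every alternative run, with log2 fold changes from −1.35 to −1.69. All 43 genes kept their direction in every fit that tested them, and all 43 were tested except 1 under the filter of 1 CPM. The number of genes past the threshold moved widely: 42 with RLE factors, 47 with upper-quartile factors (37 higher, 10 lower), 48 with limma-voom, 48 with the stricter filter, 41 without the robust option, 89 without a filter (72 higher), 509 with DESeq2 (361 higher), 959 with sample quality weights (537 higher, 422 lower), 170 with the run of mouse numbers as a block, 1056 with the Xist covariate (745 higher) and 5 against a fold change of 1.2. Alternatives chosen after seeing the data gave 579 with GC content and length offsets (399 higher, 180 lower), 1321 with these and the Xist covariate (798 higher), and 1621 with the mouse-number block and the Xist covariate (1066 higher). Without one library it ranged from 4 to 142. The lists past the threshold were 0 with an estimated correlation, 3 with fry, and from 9 to 13 without one library. The cause was not tested. The replicate number as a block gave 288 genes (173 higher, 115 lower), 41 of them among the 43; the labels name no shared litter or day, and deviations of same-numbered libraries correlated at 0.39, 0.07 and −0.17, so the numbers do not pair the samples. With this block the homeostatic (median −0.09), adult-onset, NF-kappaB and lysosome lists newly passed, and the type I interferon list no longer did (median −0.07, adjusted p = 0.17). Over 20 genes taken by the naming rule, 361 results were the same, 74 no longer passed and 3 newly passed; over 30 lists these were 636, 27 and 24. Of the results that passed in the main fit or the alternative, 0 changed the direction of the test, while several that passed in neither did, such as P2ry12 and the disease-associated, early postnatal and lysosome lists. The smallest simulated changes, under 1.5-fold, were recovered in 2% of genes, so small changes are mostly not detectable with 7 libraries.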

Other observations

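The hypothesis in this part was tested on a gene list written after the calls were seen.

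Targets of the transcription factor SRF and its actin-sensing cofactors MRTF may have risen as a group, since several genes with higher levels in cKO, such as Cnn2, Tpm4, Cfl1 and Dstn (the last chosen after its values were seen), belong to that set. Of 33 listed targets tested, 29 had a fold change above 0, 4 passed on their own and the median was 0.46. Among the 29 that did not pass on their own, 25 were above 0 and the median was 0.42, and camera gave an unadjusted p of 1.6e-09 with the preset correlation and 0.029 with an estimated correlation. For the 23 of these that are outside the actin list the estimated-correlation p was 0.027. These p-values are not adjusted for the other lists. Because the list was written after the calls were seen, leaving out the members that passed does not make the rest an independent test. The targets were not run over the 35 splits of the libraries, of which 2 gave a camera p for the actin list as small as the real one, the real one included. A rise of the targets remains a hypothesis for a separate set of mice.

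Among sterol genes, Abcg1 fell to 52.0% of the WT level. Srebf2 (log2 fold change 0.52, SE 0.12, adjusted p = 0.096), Acly (0.42, SE 0.11, adjusted p = 0.12) and Stard4 (1.01, SE 0.29, adjusted p = 0.14) of the synthesis list, and Mylip (−0.36, SE 0.10, adjusted p = 0.14) and Abca1 (−0.48, SE 0.18, adjusted p = 0.21) of the efflux list, did not pass.

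None of the 20 genes nearest to Srgap2 or to Tmem119, nor of the 14 nearest to Esr1, passed the threshold. Their log2 fold changes ranged from −1.40 to 0.38 around Srgap2 (median 0.06, SD 0.44), from −0.58 to 0.75 around Tmem119 (median 0.02, SD 0.34) and from −0.41 to 0.45 around Esr1 (median −0.01, SD 0.23), so a change of single neighbours is not excluded.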
